A study of Mus musculus with 12 samples.

How the data were processed

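Polyadenylated RNA of mouse bone marrow derived macrophages was sequenced in 12 libraries, 3 for each of 2 genotypes (wild type and Piezo1 knockout) with each of 2 treatments (PBS and C. albicans). Groups were taken from the genotype and treatment labels. The titles of the knockout PBS libraries name DMSO where their treatment label says PBS, and they were grouped as PBS. Per the submitters' processing notes, CASAVA 1.8, cutadapt 2.6, STAR 2.7.5a and DESeq2 1.34.0 were used with the mm10 build. The read counter, its strand setting and the annotation release are not given in the sources used here.

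The deposited values are TPM for 25230 genes in each of the 12 libraries, made by the authors, and each column sums to 1000000. The same table holds the authors' DESeq2 columns, named per the file headers, for 1 comparison. These are a mean normalised signal over all libraries, a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted value, all deposited by the authors. The comparison behind the authors' deposited log2 columns was identified from the values as C. albicans over PBS in wild type, since the log2 ratio of scaled reads in these groups differed from them by a median of 0.000946 over 9298 genes. Whole reads per gene were recovered from the deposited TPM and mean signal. All nonzero values (100% of 171648) lay within 0.01 of a whole read. Of the genes, 8075 had no read in any library, and the 28 genes without a symbol held 0.00132% of reads.

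Reads in genes were 17589603, 17064443 and 19165510 in wild-type PBS replicates 1 to 3 and 18643783, 22669260 and 18552916 in wild-type C. albicans. They were 25741091, 20305158 and 16400119 in knockout PBS and 21085816, 23900383 and 23384180 in knockout C. albicans. In a gene of median length 1 read was worth 0.0285 to 0.0449 TPM, which bounds what can be seen in low genes. Of the reads, 11.7% to 14.6% fell in the 10 most abundant genes of a library.

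The design fixed before the data were examined assumed counts. Since the deposited unit is TPM, its stated fallback was used: limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 mean per group, all 12 libraries and no replicate block. The wording of that fallback on the variance trend was open, and it was run with the trend on and robust estimation off, with the trend off as an alternative. Genes with at least 1 TPM in at least 3 libraries were tested, 11283 in all, with 8 residual degrees of freedom. Adjusted p-values are two-sided, by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The comparisons were the response to C. albicans in each genotype, the knockout effect with each treatment, and their interaction, which is the response in the knockout minus that in wild type.

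Of 38 gene lists fixed before the data were examined, 31 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. The response score was the mean of centred log2(TPM + 1) over genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1 in the effect averaged over genotypes, with the sign of that effect. Its difference of differences was tested by exact permutation of genotype within treatment. Named genes follow a rule fixed before the data were examined. It takes Piezo1, the 8 genes with the largest rise and the 8 with the largest fall per comparison that passed, had a mean of at least 5 TPM in the higher group and did not overlap between groups (no overlap rule for the interaction), up to 4 members of each list with the smallest p, and a panel of inflammatory genes. The examples given in the text were picked from these after their values were seen, while the alternatives were run on all of them. Of 56 genes named by the rule for fold change, 13 were under 300 bases, such as microRNA genes, with 0 to 39 reads per library, and the 5 of these given as examples, all microRNA genes, are in the closing section only.

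Gene lengths were recovered from the TPM and the reads, scaled on 234 microRNA genes, and had a Spearman correlation across genes of 0.876 with coding length plus the longest 3' UTR. Of the gene IDs, 25180 matched the reference table of GRCm38, the assembly that mm10 names, and 97.6% of tested genes had a length and a GC content. The fit was tested on simulated reads with 200 genes changed, 50 at each of 4 sizes. All libraries were simulated from the wild-type PBS levels and their spread, with as many rises as falls. At 1.5-fold the fit recovered 43 of 50 for the response in wild type, 45 in the knockout, 44 for the knockout effect with PBS, 43 with C. albicans and 35 for the interaction, and at 2-fold 50, 50, 50, 50 and 48. At 1.25-fold the numbers were 35, 37, 34, 38 and 19 in the same order. Of all calls 4 of 182, 10 of 192, 8 of 186, 6 of 187 and 7 of 159 were false. The real wild-type C. albicans libraries differed more among themselves than those of wild-type PBS, and the real changes were more numerous and not balanced in direction. These simulated figures thus do not carry over to the real comparisons.

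Alternatives fixed before the data were examined were median-ratio and upper-quartile factors, no filter and a filter at 5 TPM, CPM of at least 1 in 3 libraries, pseudocounts of 0.1 and 5, only the 6 libraries compared, the replicate number as a block, a fold minimum, an adjusted p under 0.01, other versions of the score and of the list test, and leaving out each library. Alternatives chosen after seeing the data were the fit without the variance trend, limma-voom and log2 CPM on the recovered reads, removal of a smooth trend on gene length and GC content (5 spline degrees of freedom) from each library, leaving out genes under 300 bases, and the list counts under each scaling and without wild-type C. albicans replicate 1. The plan tied DESeq2 and edgeR to deposited counts, and they were not run on the recovered reads. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library and no per-sample column was left out of the main comparisons.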

Results

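Piezo1 is a mechanically gated cation channel of the plasma membrane, and Candida albicans is a fungus that grows as yeast and as hyphae. Polyadenylated RNA was sequenced from mouse bone marrow derived macrophages, cells grown from marrow with M-CSF, of wild-type and Piezo1 knockout genotype. Each genotype received either PBS or C. albicans, by the treatment labels, with 3 libraries in each of the 4 groups and 12 in all. The titles of the knockout PBS libraries name DMSO instead, and which vehicle they received is not given in the sources used here. A vehicle effect in them would enter the knockout effect with PBS, the response in the knockout and the interaction, while the knockout effect with C. albicans compares other libraries. The series addresses whether Piezo1 takes part in the macrophage response to the fungus. Reads assigned to genes ranged from 16400119 to 25741091 per library, and 11283 genes reached 1 TPM (transcript abundance scaled to library and gene length) in at least 3 libraries and were tested. The first principal component of the 1000 most variable genes held 45.9% of the variance and separated C. albicans from PBS in both genotypes, with the knockout C. albicans libraries between 3.09 and 4.01 and those of wild type between 19.3 and 24.0. Wild-type C. albicans replicate 1 stood apart from its group, with a chi-square per degree of freedom of 16.2 and 15.3 against its replicates, where all other replicate pairs lay between 1.49 and 4.6. Nothing in the labels says that replicates came from separate animals or cultures, so all p-values measure only the spread between these libraries. The labels give neither the dose of fungus nor the duration of exposure.

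Piezo1 (gene 234839, chromosome 8, 122481698 to 122551329 in GRCm38) was detected in every library, at a lower level in the knockout. Its level was 135 ± 4.69 TPM (SD, n = 3) in wild-type cells with PBS and 137 ± 8.68 with C. albicans. In the knockout it was 65.4 ± 2.72 with PBS and 64.9 ± 0.756 with C. albicans, or 48.6% and 47.4% of the wild-type mean. The log2 fold change was -1.03 with PBS (SE 0.05, adjusted p = 6.1e-08) and -1.06 with C. albicans (SE 0.05, adjusted p = 3.4e-08), and no library of one genotype overlapped the other. Gene-level values do not show which exons were read. They do not tell a deletion of some exons from a deletion in part of the cells or of 1 allele, and knockout is the word of the labels. Between the treatments in wild type Piezo1 did not pass, with a log2 fold change of 0.02 (adjusted p = 0.727), while in the authors' deposited table it stood at 0.10 with an adjusted p of 0.0462. With median-ratio factors, the scaling DESeq2 uses, the value was 0.10 as well (adjusted p = 0.0769, and 0.00349 to 0.999 over the alternatives), so the fold changes differed by scaling. Lyz2, the main macrophage lysozyme (chromosome 10, 117277541 to 117282272), fell by 1.11 on the log2 scale in the knockout with PBS, to 46.2% of wild type. With C. albicans Lyz2 was at 58.0% of wild type. Its neighbour and paralog Lyz1 (chromosome 10, 117287795 to 117292868) rose by 1.51 and 1.45, from a mean of 10.6 TPM in wild-type cells with PBS to 31.8 in the knockout. Lyz1 and Lyz2 are close copies, so the split of reads between them is uncertain.

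**Figure D1:**
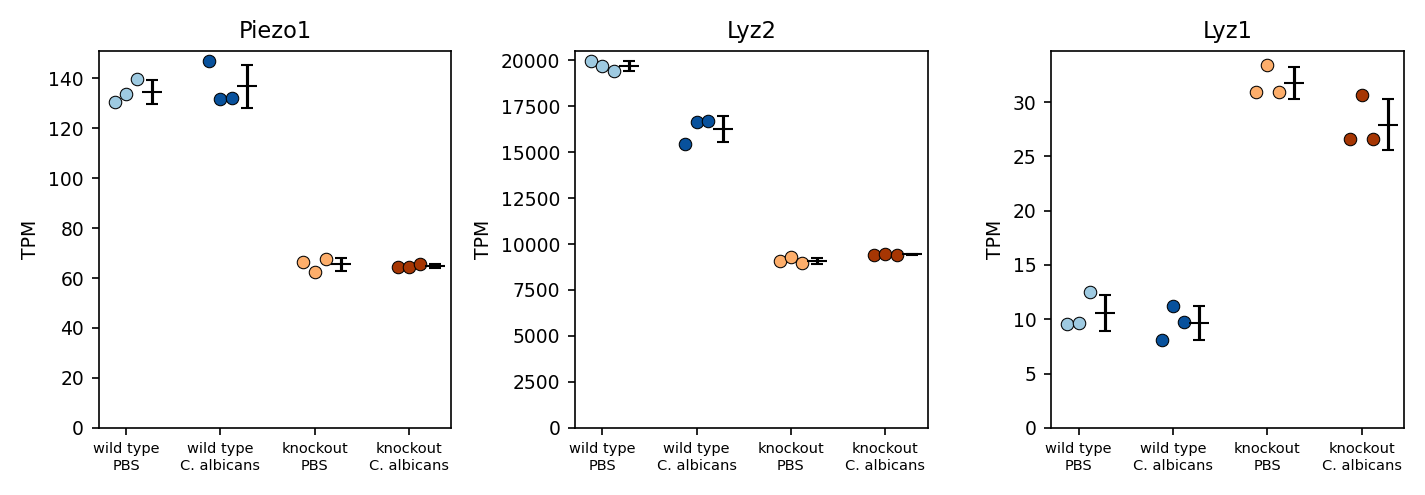
TPM of Piezo1, Lyz2 and Lyz1 in each of the 12 libraries by group. Points are libraries and the bar beside them is the mean with the SD of 3 libraries. Piezo1 lay between 62.4 and 67.5 TPM in the 6 knockout libraries and between 130.4 and 146.9 in the 6 wild-type libraries.

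In wild-type macrophages C. albicans raised cytokines, chemokines and NF-kB feedback genes. Cxcl2, a neutrophil-attracting chemokine, rose by 6.25 on the log2 scale (SE 0.10, adjusted p = 4.3e-13), from 6.86 ± 0.870 to 594 ± 40.9 TPM (SD, n = 3). The related Cxcl1 rose by 4.88, Tnf, encoding tumour necrosis factor, by 3.62 and Il1b, encoding interleukin-1 beta, by 3.37. Socs3, an inhibitor of cytokine signalling, rose by 3.80, Gpr84, a receptor for medium-chain fatty acids, by 3.44 and Tnfsf9, a ligand of the TNF family, by 3.42. Among genes that fell, Ier5l fell by 1.78, the cytosolic glycosidase gene Engase by 1.74, Arrdc3, an arrestin-like gene, by 1.48, Thbd, encoding thrombomodulin, by 1.46, the adhesion gene Cadm1 by 1.40 and Gdf3, of the TGF-beta family, by 1.40. In all, 5006 genes changed at an adjusted p under 0.05, 1814 higher and 3192 lower, and 284 of them changed at least 2-fold, 231 higher and 53 lower. The share that was higher depended on scaling. It was 36.2% with the TPM values as deposited, 55.0% with median-ratio factors (2559 higher and 2091 lower) and 38.7% with upper-quartile factors. In the authors' deposited table, from their DESeq2 test of this comparison, 4443 of 13587 genes had an adjusted p under 0.05, 2526 higher and 1917 lower. The authors' deposited table gives a log2 fold change of 6.51 for Cxcl2 and 3.73 for Tnf. Its values of 9.33 for Cxcl1 and 3.77 for Il1b are larger than those on the log2(TPM + 1) scale. At least 2-fold it has 566 genes, 384 higher and 182 lower.

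The fixed gene lists showed which parts of the response moved together in wild type. All 23 tested NF-kB feedback and target genes rose, with a median of 1.64 (camera adjusted p = 1.2e-31, 23 higher and 0 lower adjusted over the list alone). Nfkbiz, encoding an inducible nuclear cofactor of NF-kB, rose by 3.78 and Nfkbia, which encodes the inhibitor IkB-alpha, by 2.62. Of 14 inflammatory cytokines 11 rose and 1 fell (12 higher and 1 lower adjusted over the list alone), among them Il10, encoding an anti-inflammatory cytokine, at 2.26. Of 19 chemokines 12 rose and 4 fell (12 higher and 4 lower adjusted over the list alone), with Ccl2 at 1.99, Ccl3 at 2.05 and Ccl4 at 1.78. Of 28 immediate early and calcium-NFAT genes 20 rose and 3 fell (21 higher and 3 lower adjusted over the list alone), including Maff at 2.7 and the MAP kinase phosphatase gene Dusp4 at 2.28. These 4 lists passed camera with an estimated correlation as well. Of 22 NRF2 targets, genes of the oxidative stress response, 17 rose and 2 fell (17 higher and 2 lower adjusted over the list alone), with Slc7a11, encoding a cystine transporter, at 2.34 and Txnrd1, encoding thioredoxin reductase, at 1.28. That list had a camera adjusted p of 7.9e-07 and an adjusted p = 0.289 with an estimated correlation.

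Receptors and signalling genes for fungi moved less evenly in wild type. Of 22 fungal recognition receptors 11 rose and 4 fell (11 higher and 4 lower adjusted over the list alone). Clec4e, encoding the C-type lectin Mincle, rose by 3.21 and Tlr2 by 1.89, while Mrc1, encoding the mannose receptor, fell by 0.66. Clec7a, encoding the beta-glucan receptor Dectin-1, rose by 0.21, and Clec4n, encoding Dectin-2, had a log2 fold change of 0.12 that did not pass (adjusted p = 0.353). Of 27 genes of C-type lectin signalling 13 rose and 8 fell (13 higher and 8 lower adjusted over the list alone), with Malt1 at 1.94 and the kinase gene Syk at 0.30, and the adaptor gene Card9 fell by 0.39. The receptor list had an adjusted p = 0.124 and the signalling list an adjusted p = 0.132 with an estimated correlation, after camera adjusted p of 0.00251 and 0.0158 with the preset one. Of 21 inflammasome genes 6 rose and 5 fell (6 higher and 5 lower adjusted over the list alone), led by Nlrp3, an inflammasome sensor, at 2.49. The camera adjusted p of that list was 0.0158, with an adjusted p = 0.106 with an estimated correlation. Of 19 antimicrobial effectors 6 rose and 4 fell (7 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.192). Ptgs2, encoding cyclooxygenase-2, rose by 3.16, Acod1, the itaconate-producing enzyme gene, by 2.72 and Nos2, encoding inducible nitric oxide synthase, by 1.92, and Saa3 fell by 1.14. Of 25 macrophage identity genes 3 rose and 12 fell (5 higher and 12 lower adjusted over the list alone), including Fcgr3, which fell by 0.65. With median-ratio factors that count was 8 higher and 9 lower, and its camera adjusted p was 0.204. Of 37 interferon response genes 9 rose and 8 fell (9 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.151), with the transcription factor gene Irf1 at 1.35, and without wild-type C. albicans replicate 1 the count was 21 higher and 6 lower. Il6, Il12b and Il23a stayed under the filter and were not tested. In the authors' deposited DESeq2 test of this comparison Il6 was higher, with a log2 fold change of 5.79 (SE 1.51, adjusted p = 7.2e-04). Its reads were 0 in each wild-type PBS library and 3, 24 and 7 in wild-type C. albicans replicates 1 to 3.

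In Piezo1 knockout macrophages C. albicans raised chemokine, cytokine and NF-kB feedback genes. Cxcl2 rose by 4.8 on the log2 scale (SE 0.10, adjusted p = 1.2e-11), from 10.0 ± 1.77 to 304 ± 13.1 TPM (SD, n = 3). Socs3 rose by 2.97, Nfkbiz by 2.97, Cxcl1 by 2.97, Tnf by 2.74, Tnfsf9 by 2.72 and Il1b by 2.31. Thbd fell by 0.66, the lipocalin gene Lcn2 by 0.60, Timp1, encoding an inhibitor of metalloproteinases, by 0.56 and the receptor gene Mrgpre by 0.53. In all, 799 genes changed, 445 higher and 354 lower, and 78 changed at least 2-fold, 77 higher and 1 lower. The share that was higher was 55.7% with TPM, 77.4% with median-ratio factors (605 higher and 177 lower) and 65.1% with upper-quartile factors (501 higher and 268 lower). The count fell whichever knockout library was left out. It was 464, 626 and 420 without knockout PBS replicates 1, 2 and 3, and 468, 532 and 441 without knockout C. albicans replicates 1, 2 and 3. With only its own 6 libraries in the fit it was 1350.

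By list, 22 of 23 NF-kB feedback and target genes rose in the knockout (23 higher and 0 lower adjusted over the list alone), with a median of 1.02 (camera adjusted p = 8.7e-52) and Nfkbia at 1.87. Of 14 inflammatory cytokines 7 rose and 0 fell (7 higher and 0 lower adjusted over the list alone), with Il10 at 1.28. Of 19 chemokines 10 rose and 2 fell (11 higher and 3 lower adjusted over the list alone), with Ccl2 at 1.39 and Ccl3 at 1.42. Of 28 immediate early and calcium-NFAT genes 17 rose and 0 fell (18 higher and 0 lower adjusted over the list alone), with Maff at 2.17 and Dusp4 at 1.31. Of 22 fungal recognition receptors 6 rose and 1 fell (6 higher and 2 lower adjusted over the list alone), with Tlr2 at 1.46, Clec4e at 1.65 and Itgam, encoding the integrin chain CD11b, at 0.43. Of 21 inflammasome genes 4 rose and 0 fell (5 higher and 2 lower adjusted over the list alone), with Nlrp3 at 2.04. Of 25 macrophage identity genes 8 rose and 1 fell (9 higher and 1 lower adjusted over the list alone). These 7 lists passed camera with both correlations. Of 21 antigen presentation genes 7 rose and 1 fell (7 higher and 4 lower adjusted over the list alone), among them the MHC class II genes H2-Aa at 0.50 and H2-Ab1 at 0.57 and the invariant chain gene Cd74 at 0.43. That list had a camera adjusted p of 0.0124 and an adjusted p = 0.196 with an estimated correlation. Of 22 NRF2 targets 2 rose and 1 fell (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.190). Malt1 rose by 0.84, Acod1 by 1.61 and Ptgs2 by 1.83, while Nos2 at 0.40, Syk at 0.00 and Clec7a at 0.09 did not pass. Between the genotypes, 383 genes rose in both responses and 280 fell in both, against 71.5 and 100.1 for independent lists, and 27 changed in opposite directions.

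With PBS alone, knockout macrophages differed from wild type in Lyz2, Lyz1, Piezo1 and other genes. Cav1, encoding caveolin-1, rose by 1.36 on the log2 scale (SE 0.14, adjusted p = 2.6e-05), the G protein subunit gene Gng4 by 0.89 and Npy, encoding neuropeptide Y, by 0.88, to 967 ± 19.4 TPM from 526 ± 9.41 (SD, n = 3). The ubiquitin ligase genes Mid1 and Cbl fell by 1.41 and 1.38, Cadm1 by 1.35, Zbed6 by 1.17, Ghrl, encoding ghrelin, by 1.17, Erdr1 by 1.12 and the aminopeptidase gene Lnpep by 1.12. Zbed6 lies inside an intron of another gene, Zc3h11a, so its reads are uncertain. In all, 3641 genes changed, 693 higher and 2948 lower, and 41 changed at least 2-fold, 11 higher and 30 lower. The share that was higher was 19.0% with TPM, 49.5% with median-ratio factors (1577 higher and 1608 lower) and 41.1% with upper-quartile factors (1293 higher and 1853 lower), so the balance of directions depended on scaling. Fold change fell with gene length across genes, with a Spearman correlation of -0.462, and among the 2821 longest genes 23 were higher and 1517 lower, against 442 and 174 among the 2821 shortest. Genes are not independent replicates in that correlation.

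With PBS, inflammatory genes differed in either direction between genotypes or did not pass. Tnf had a log2 fold change of 0.06 (adjusted p = 0.427) and Il1b of 0.15 (adjusted p = 0.599), while Cxcl2 rose by 0.48, Cxcl1 by 0.64 and Il10 by 0.35. Of 14 cytokines 2 were higher and 1 lower (2 higher and 1 lower adjusted over the list alone), which became 0 higher and 1 lower with the length and GC trend removed, and of 23 NF-kB genes 1 was higher and 5 lower (1 higher and 5 lower adjusted over the list alone). Of 22 fungal recognition receptors 5 were higher and 9 lower (5 higher and 9 lower adjusted over the list alone), which turned to 7 higher and 6 lower with median-ratio factors. Itgam fell by 0.80, Mrc1 by 0.69 and Tlr2 by 0.50, and Clec7a, Clec4n and Card9 did not pass, at 0.04, -0.19 and -0.05. Of 27 C-type lectin signalling genes 0 were higher and 17 lower (1 higher and 18 lower adjusted over the list alone), including the exchange factor gene Vav1, which fell by 0.40, Ptpn11, which fell by 0.38, and Pik3r1, which fell by 0.46. With median-ratio factors 1 was higher and 12 lower, and the camera adjusted p was 0.00138, with an adjusted p = 0.171 with an estimated correlation. Of 37 interferon response genes 0 were higher and 22 lower (0 higher and 24 lower adjusted over the list alone), among them Oas2 and Dhx58, which fell by 0.31 and 0.26. With median-ratio factors 2 were higher and 6 lower, and the camera adjusted p of 0.00228 became an adjusted p = 0.821 with an estimated correlation. Of 25 macrophage identity genes 3 were higher and 12 lower (3 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0413), with an adjusted p = 0.171 with an estimated correlation. Of 21 inflammasome genes 0 were higher and 10 lower (0 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.207), and Nlrp3 fell by 0.70. Cybb, encoding the catalytic subunit of the phagocyte NADPH oxidase, fell by 0.70.

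NRF2 targets and oxidative phosphorylation genes were more often higher than lower in the knockout with PBS. Of 22 NRF2 targets 7 were higher and 1 lower (7 higher and 1 lower adjusted over the list alone), or 12 and 1 without wild-type C. albicans replicate 1 in the fit, with Gstm1, a glutathione transferase gene, at 0.48, Taldo1 at 0.35 and the ferritin gene Ftl1 at 0.33. The camera adjusted p of that list was 9.3e-07, with an adjusted p = 0.526 with an estimated correlation. Of 32 oxidative phosphorylation genes 10 were higher and 3 lower (10 higher and 3 lower adjusted over the list alone), with Cox6c at 0.25, Ndufa4 at 0.17 and Cox5a at 0.13. That list had a camera adjusted p of 3.5e-04 and an adjusted p = 0.0512 with an estimated correlation. Its direction turned when the trend on gene length and GC content was removed, to 2 higher and 7 lower, and Cox5a then had a value of -0.03.

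With C. albicans, knockout macrophages had lower levels of inflammatory transcripts than wild type. Tnf fell by 0.82 on the log2 scale (SE 0.06, adjusted p = 4.1e-07), from 559 ± 30 to 316 ± 13.3 TPM (SD, n = 3). Clec4e fell by 1.72, Acod1 by 1.75, Nos2 by 1.73, the prostaglandin synthase gene Ptges by 1.8, Hivep3 by 1.74, Cxcl1 by 1.26 and Cxcl2 by 0.96. For some of these genes part of the difference was present with PBS. The responses of Acod1 and Hivep3 differed by only -1.11 and -0.83 between genotypes. Those of Tnf, Cxcl1 and Cxcl2 differed by -0.89, -1.91 and -1.44, more than their levels with C. albicans. Hspa1a and Hspa1b, near-identical heat shock genes whose reads cannot be told apart with certainty, fell by 2.24 and 2.02 (SE 0.52 and 0.53). Ier5l rose by 1.27, Gdf3 by 1.10, Engase by 1.07, the centromere protein gene Cenpa by 0.97 and Npdc1 by 0.92. In all, 4503 genes changed, 1402 higher and 3101 lower, and 121 changed at least 2-fold, 12 higher and 109 lower. The share that was higher was 31.1% with TPM, 46.7% with median-ratio factors (2158 higher and 2463 lower) and 52.4% with upper-quartile factors (2468 higher and 2245 lower). Fold change again fell with gene length, with a Spearman correlation across genes of -0.400. The correlation with GC content was 0.322 here, 0.0890 with PBS, -0.342 and -0.189 for the responses of wild type and knockout and 0.281 for the interaction.

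All 23 NF-kB feedback and target genes were lower in the knockout with C. albicans (0 higher and 23 lower adjusted over the list alone), under each scaling tried, with a median of -0.78 (camera adjusted p = 8.7e-16). Cflar, encoding the caspase-8 regulator cFLIP, fell by 1.12 and the adhesion gene Icam1 by 1.00. Of 14 cytokines 0 were higher and 10 lower (0 higher and 11 lower adjusted over the list alone), with Il1b lower at -0.91 and Il10 at -0.63. Of 19 chemokines 4 were higher and 11 lower (4 higher and 11 lower adjusted over the list alone), with Ccl2 at -0.72, Ccl3 at -0.81 and Cxcl10 at -1.46. Of 28 immediate early and calcium-NFAT genes 3 were higher and 16 lower (3 higher and 19 lower adjusted over the list alone), with Dusp4 at -1.20. For these 3 lists the adjusted p with an estimated correlation was 0.135, 0.148 and 0.148, after camera adjusted p of 0.00202, 0.0491 and 0.00204. Of 27 C-type lectin signalling genes 0 were higher and 20 lower (1 higher and 21 lower adjusted over the list alone), with Malt1 at -0.95, Syk at -0.43 and Vav1 at -0.39, and the list passed with both correlations. Of 22 fungal recognition receptors 3 were higher and 12 lower (3 higher and 12 lower adjusted over the list alone), with Tlr2 at -0.93, while Clec7a at -0.09, Clec4n at -0.16 and Card9 at 0.16 did not pass. That list had a camera adjusted p of 0.0440 and an adjusted p = 0.271 with an estimated correlation. Of 21 inflammasome genes 1 was higher and 10 lower (1 higher and 10 lower adjusted over the list alone), with Nlrp3 at -1.15, and the camera adjusted p of 0.0201 became an adjusted p = 0.144 with an estimated correlation. Of 37 interferon response genes 2 were higher and 25 lower (2 higher and 28 lower adjusted over the list alone), with a camera adjusted p of 0.00142 and an adjusted p = 0.465 with an estimated correlation. Cybb stood at -0.77. Part of the lower levels of Cflar, Cxcl10 and Nlrp3 was present with PBS, since their responses differed by only -0.54, -0.88 and -0.45. For Il1b and Il10 the responses differed by -1.06 and -0.98, more than the levels with C. albicans.

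Some fixed lists had more genes higher than lower in the knockout with C. albicans. H2-Aa rose by 0.53 and H2-Ab1 by 0.57, and of 21 antigen presentation genes 9 were higher and 5 lower (9 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0491, with an adjusted p = 0.334 with an estimated correlation). Its median was 0.04 and its mean just under 0, and with the length and GC trend removed the count turned to 7 higher and 8 lower. Of 32 oxidative phosphorylation genes 10 were higher and 0 lower (10 higher and 0 lower adjusted over the list alone), with Cox4i1 at 0.17 and Ndufv1 at 0.22, and the list passed with both correlations. With the length and GC trend removed 4 were higher and 4 lower and Cox4i1 had a value of -0.04, and without wild-type C. albicans replicate 1 the count was 16 higher and 1 lower. Of 30 lysosome and autophagy genes 14 were higher and 6 lower (15 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00347, with an adjusted p = 0.372 with an estimated correlation). The median of that list was 0.08 and its mean just under 0, and with the length and GC trend removed 11 were higher and 7 lower. Of 11 tested genes in a fixed list of chromosomal neighbours of Piezo1 5 were higher and 1 lower (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0164, with an adjusted p = 0.307 with an estimated correlation), which turned to 1 higher and 3 lower with that trend removed. Of 25 macrophage identity genes 12 were higher and 9 lower (12 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.148), which turned to 5 higher and 12 lower with it removed. Between the treatments, 264 genes were higher in the knockout in both and 1807 lower in both, against 86.1 and 810.2 for independent lists, and 205 changed in opposite directions.

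**Figure D2:**
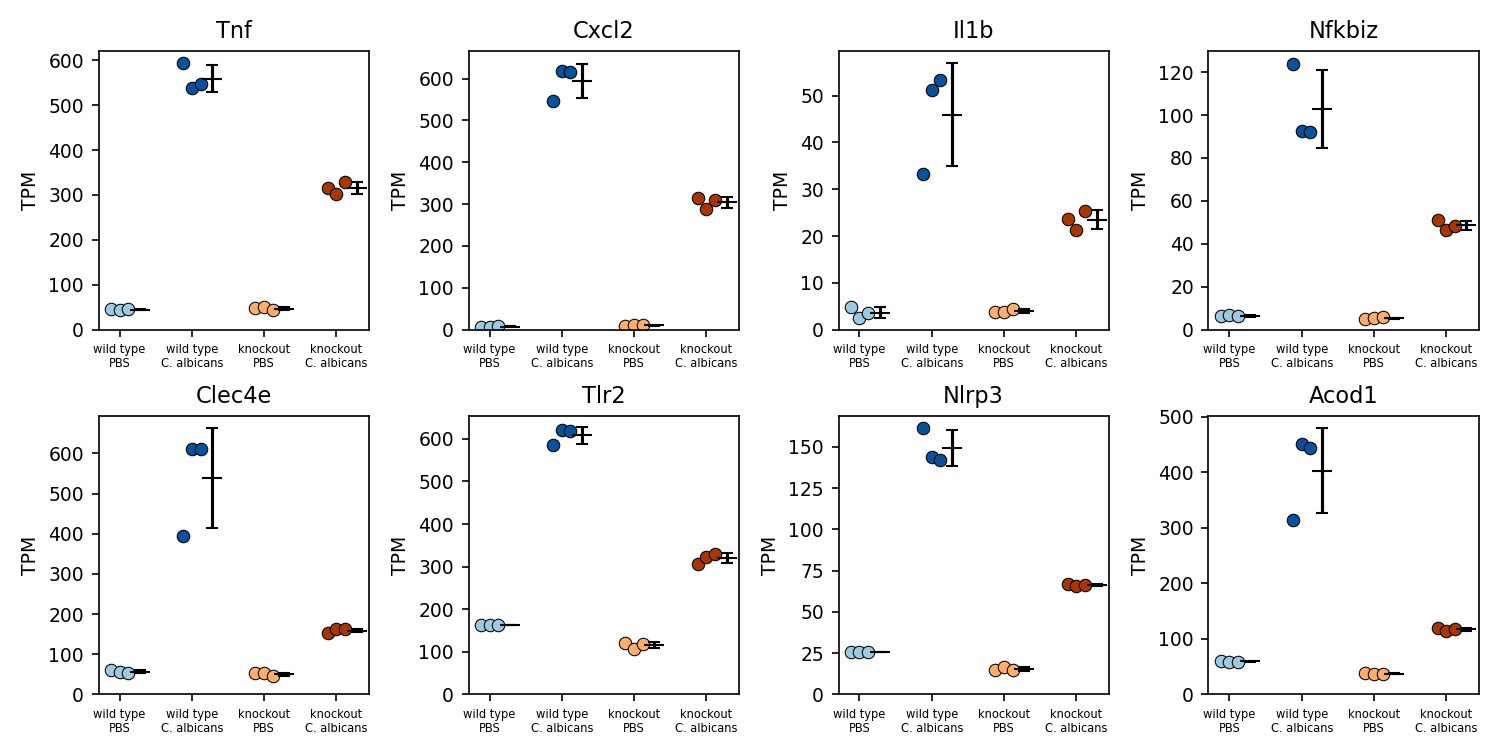
TPM of 8 response genes in each of the 12 libraries by group. Points are libraries and the bar beside them is the mean with the SD of 3 libraries. In each panel the knockout C. albicans libraries lie below the wild-type C. albicans libraries.

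The interaction test asked directly whether the response to C. albicans differed between genotypes, and inflammatory genes responded less in the knockout. The response of Tnf was smaller by a log2 value of -0.89 (SE 0.08, adjusted p = 2.1e-05), that of Cxcl2 by -1.44, Cxcl1 by -1.91, Cxcl3 by -1.95, Il1b by -1.06, Il10 by -0.98, Clec4e by -1.56, Ptgs2 by -1.33, Acod1 by -1.11 and Nos2 by -1.52. For Cxcl2 and Cxcl1 these values include a higher level in the knockout with PBS, by 0.48 and 0.64. Cav1 had the value -2.18, since it rose with C. albicans in wild type from 10.2 to 46.0 TPM and was at 27.6 and 24.8 in the knockout. In the other direction stood Erdr1 at 1.54, Cadm1 at 1.5, Ier5l at 1.41 and Gdf3 at 1.37. Erdr1 and Cadm1 were already lower in the knockout with PBS, which makes up most of their values. In all, 1563 genes passed, 849 higher and 714 lower, and 91 differed at least 2-fold, 35 higher and 56 lower. The share that was higher was 54.3% with TPM, 41.6% with median-ratio factors (669 higher and 938 lower) and 59.2% with upper-quartile factors. The count was 2531 without wild-type C. albicans replicate 1 and 1036 without knockout PBS replicate 1. The count at 2-fold was 149 without wild-type C. albicans replicate 1.

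Of 23 NF-kB feedback and target genes 21 had a smaller response in the knockout and 0 a larger one (0 higher and 22 lower adjusted over the list alone), with a median of -0.67 (camera adjusted p = 2.7e-25). Tnfaip2 stood at -0.61, Tnip1 at -0.64 and Nfkb2 at -0.73. Of 14 cytokines 0 were higher and 7 lower (1 higher and 9 lower adjusted over the list alone), of 19 chemokines 3 higher and 10 lower (3 higher and 11 lower adjusted over the list alone), with Ccl2 at -0.60 and Ccl3 at -0.63. Of 28 immediate early and calcium-NFAT genes 1 was higher and 11 lower (2 higher and 17 lower adjusted over the list alone), with Dusp1 at -0.76, Dusp4 at -0.97 and Fos at -0.92. Of 25 macrophage identity genes 12 were higher and 1 lower (16 higher and 4 lower adjusted over the list alone), with Fcgr3 at 0.65, Itgam at 0.45 and Aif1 at 0.58, where the corresponding transcripts fell less or rose more in the knockout. These 5 lists passed camera with both correlations. The macrophage identity list had a median of -0.22 in the knockout with PBS and 0.0565 with C. albicans. Lower levels in the knockout with PBS therefore enter its interaction, and the titles of those PBS libraries name DMSO. Of 22 NRF2 targets 1 was higher and 9 lower (1 higher and 15 lower adjusted over the list alone), or 1 and 17 without wild-type C. albicans replicate 1, with Slc7a11 at -1.68, Txnrd1 at -0.98 and Prdx1 at -0.49, and the camera adjusted p of 1.8e-07 became an adjusted p = 0.244 with an estimated correlation. Of 21 antigen presentation genes 7 were higher and 3 lower (9 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0733), with H2-Ab1 at 0.63 and H2-Eb1 at 0.81. Malt1 stood at -1.10, Syk at -0.30, Tlr2 at -0.43 and Nlrp3 at -0.45, within C-type lectin, receptor and inflammasome lists that did not pass camera (adjusted p = 0.0733, 0.131 and 0.0733). Of 37 interferon response genes 3 were higher and 0 lower (2 higher and 0 lower adjusted over the list alone), although the median was -0.12, and without wild-type C. albicans replicate 1 the counts were 4 higher and 16 lower.

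**Figure D3:**
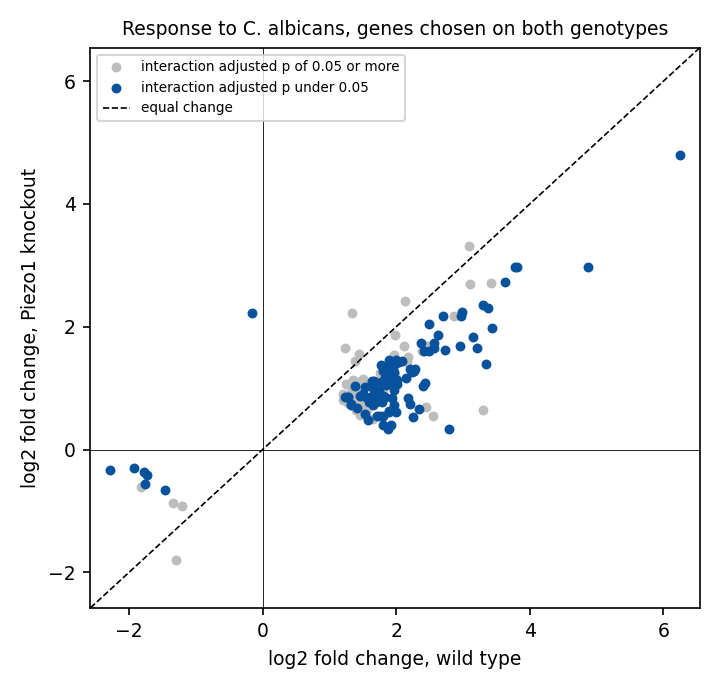
Log2 fold change with C. albicans in wild type (x axis) and in the Piezo1 knockout (y axis) for the 154 response genes, chosen on the effect averaged over genotypes. Each point is a gene, blue where the interaction passed, and the dashed line marks equal change. Of the 144 genes that rose, 137 had the larger change in wild type.

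A response score summarised the 154 genes that changed at least 2-fold in the effect averaged over genotypes, 144 risen and 10 fallen. These genes were chosen on the same libraries, so the rise itself is not independent evidence. With C. albicans the score rose by 2.0 in wild type and by 1.20 in the knockout, a ratio of 0.60. The difference of differences was -0.80, and the planned exact permutation test of genotype within treatment did not pass (two-sided p = 0.0900 over 400 arrangements, of which the smallest possible is 0.005). That p cannot decide on the difference, since the score with PBS differed by only -0.03 between genotypes. Arrangements that part the C. albicans libraries by genotype therefore gave similar differences, 36 of 40 as large as the observed one. Among the 144 risen genes, which include the cytokine and chemokine genes above, the interaction passed for 96, and 95 of these responded less in the knockout. The median ratio of knockout to wild-type log2 change was 0.604. With PBS the mean score was -0.79 in wild type and -0.82 in the knockout. For the 10 fallen genes alone the score with PBS was -0.81, -0.91 and -0.85 in the wild-type libraries and -0.26, -0.20 and -0.49 in the knockout ones, so the PBS libraries also enter their difference of differences of -0.98. Several of these fallen genes are microRNA genes. With genes under 300 bases left out of the fit, 133 response genes were chosen and the difference of differences was -0.85. Genes whose 3 libraries of one group did not overlap those of the other numbered 5742, 3726, 5205 and 5562, or 50.9%, 33.0%, 46.1% and 49.3%, for the responses of wild type and knockout and the knockout effect with PBS and C. albicans, where chance gives 10%.

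**Figure D4:**
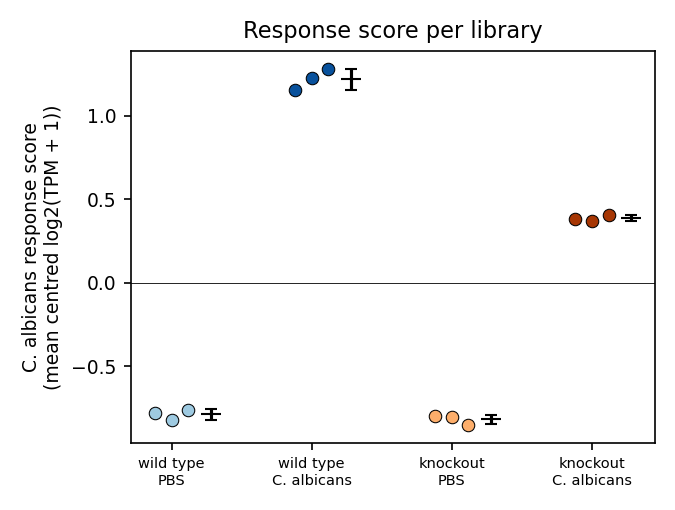
Response score of each of the 12 libraries, the mean over 154 genes of centred log2(TPM + 1) with the sign set by the direction of the response. Points are libraries and the bar beside them is the mean with the SD of 3 libraries. The knockout C. albicans libraries sit between 0.371 and 0.406 and the wild-type ones between 1.15 and 1.28.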

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

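The tests on wild-type C. albicans replicate 1, the Lyz1 and Lyz2 reads, the macrophage list with C. albicans, the Lyz2 allele, the slopes of single libraries and the shared batch were chosen after the results were seen.

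A difference between the genotypes in the response to C. albicans, by the interaction test, singled out 90 of the genes given as examples, and each value is the log2 response in the knockout minus that in wild type. Negative values, 56 in number, were those of Mir7687 at -3.46, Hspa1a at -2.45, Mir21a at -2.44, Cav1 at -2.18, AA467197 at -2.14, Cxcl3 at -1.95, Cxcl1 at -1.91, Ptges at -1.72, Slc7a11 at -1.68, S100a8 at -1.66, Clec4e at -1.56, Nos2 at -1.52, Gpr84 at -1.46, Cxcl2 at -1.44, Ptgs2 at -1.33, Cd24a at -1.32, Acod1 at -1.11, Malt1 at -1.10, Il1b at -1.06, Il10 at -0.98, Txnrd1 at -0.98, Dusp4 at -0.97, Plaur at -0.92, Fos at -0.92, Tnf at -0.89, Npy at -0.88, Cxcl10 at -0.88 and Hivep3 at -0.83. The remaining negative values were those of Socs3 at -0.83, Sqstm1 at -0.82, Nfkbiz at -0.82, Dusp1 at -0.76, Nfkbia at -0.75, Nfkb2 at -0.73, Icam1 at -0.71, Tnip1 at -0.64, Gng4 at -0.63, Ccl3 at -0.63, Tnfaip2 at -0.61, Ccl2 at -0.60, Cflar at -0.54, Maff at -0.53, Itga5 at -0.53, Prdx1 at -0.49, Nlrp3 at -0.45, Tlr2 at -0.43, Ccl4 at -0.40, Actg1 at -0.32, Lats1 at -0.32, Flna at -0.31, Cox6c at -0.31, Syk at -0.30, Vcl at -0.27, Taldo1 at -0.27, Iqgap1 at -0.26 and Ftl1 at -0.12. Positive values, 34 in number, were those of Mir339 at 3.31, Mir199a-1 at 2.38, Mir1934 at 2.21, Erdr1 at 1.54, Cadm1 at 1.5, Ier5l at 1.41, Gdf3 at 1.37, Tmem176b at 1.35, Engase at 1.33, Mid1 at 1.12, Arrdc3 at 1.02, Cd79a at 0.96, Saa3 at 0.84, H2-Eb1 at 0.81, Thbd at 0.80, Npdc1 at 0.69, Mrgpre at 0.67, Mrc1 at 0.66, Fcgr3 at 0.65, Cd4 at 0.64, H2-Ab1 at 0.63, Timp1 at 0.59, Aif1 at 0.58, H2-Aa at 0.51, Cd74 at 0.49, Itgam at 0.45, Acp5 at 0.40, Irf7 at 0.38, Csf3r at 0.36, Lyz2 at 0.33, Atp6v0d2 at 0.26, Ndufv1 at 0.24, Dhx58 at 0.20 and Ctsd at 0.19. The microRNA genes among them are short and rest on 0 to 13 reads per library.

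The response to C. albicans was smaller in the knockout, by a score difference of -0.80 that the planned permutation test did not separate from other arrangements (exact two-sided p = 0.0900). Of the 36 arrangements with a difference as large, all 36 kept the C. albicans libraries parted by genotype, and 40 such arrangements exist. The score with PBS differed by only -0.03 between genotypes, so such arrangements give similar differences and this p does not decide. Scaling and a length or GC trend are argued against as causes, since the difference was -0.82 with median-ratio factors and -0.80 with the trend removed, and it was -0.91 without wild-type C. albicans replicate 1. Lower exposure to the fungus in the knockout wells could give the same picture and was not tested, as the labels carry no measure of dose, nor was DMSO in the knockout controls. The lower level of Piezo1 stays open as a biological explanation and is a hypothesis here.

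Lyz2 was lower and Lyz1 higher in the knockout. Reads moved between these paralogs are argued against for the fall of Lyz2, since the sum of the depth-scaled reads of both genes was at most 0.615 of the wild-type level. For the rise of Lyz1, a fixed share of Lyz2 reads moved to it is argued against. Lyz1 rose by 1.51 with PBS and 1.45 with C. albicans while Lyz2 fell to 46.2% and 58.0%. A share that grew in the knockout cannot be told apart from a higher level, since the gain of Lyz1 was at most 0.286% of the Lyz2 reads. A general loss of macrophage transcripts stays open with PBS, where the macrophage identity list had a median of -0.22, too near the bound of -0.25 to decide. With C. albicans the median was 0.0565 and Lyz2 was still at 58.0% of wild type, which argues against such a loss for the TPM values as deposited. With the length and GC trend removed more genes of that list were lower than higher, so the argument depends on the processing. An altered Lyz2 allele carried with the knockout, such as a recombinase inserted at Lyz2, is a candidate explanation. Lyz2 was at 0.462 of wild type with PBS and 0.581 with C. albicans. These ratios differed by the interaction test (0.33, adjusted p = 1.7e-04), so an allele that takes away a fixed share would not account for both by itself. The bounds for this explanation were written after the values were seen, so meeting them decides nothing. The labels do not say how the knockout was made, and an effect of Piezo1 on Lyz2 also stays open.

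More genes were lower than higher in the knockout, long genes most. Scaling is a candidate explanation for the imbalance, as 49.5% of changed genes were higher with PBS under median-ratio factors, but those factors centre the median and so do not show which scaling is right. A length or GC trend is argued against as the whole cause of the changed genes, since 3641 genes changed before and 3051 after its removal, and 2394 changed the same way in both. Slopes of log2 TPM on log2 length in all 6 knockout libraries lay below those of all 6 wild-type libraries. The gap was 0.0160, against a largest SD within a group of 0.0153. The lower slopes were thus not confined to single libraries. The bound for RNA quality of single libraries, a gap above that SD, was written after the values were seen, so meeting it decides nothing. A batch shared by all libraries of a genotype cannot be told apart from the genotype, as the same gap of 0.0160 would arise from either, and a biological effect on long genes stays open and untested.

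For the response in wild type 5006 genes changed in the real grouping and at most 2 in any other split of the 6 libraries, and 1 of 10 splits reached the real number. For the response in the knockout the values were 799 and 0, for the knockout effect with PBS 3641 and 1, and with C. albicans 4503 and 1, each with 1 of 10 splits. These splits are too few for a share under 0.05. Each other split also mixes the 2 groups, which moves the real difference into the spread within groups. Their low counts were thus fixed in advance and do not decide on chance. For the interaction 3 of 100 regroupings of genotype within treatment gave at least 1563 genes, the real one included, and the highest other gave 5163. This share does not decide on chance, although the bound set beforehand was 0.05, since regrouping also breaks the genotype effects of 3641 and 4503 genes and so widens the spread within groups. Of the 8 regroupings drawn that parted the C. albicans libraries by genotype 3 gave as many, the real one included, and the other 92 gave at most 230 genes. The highest other exchanged the genotype labels in 1 treatment only, which turns the knockout effect itself into an interaction and so points to the structure of the samples.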

How the results depend on the processing

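The fits without the variance trend, on recovered reads, with the length and GC trend removed and without short genes were chosen after the results were seen. Over 614 results for genes named by the rule, 14084 alternative values were compared with the main fit. Of these 12946 stayed on the same side of the threshold, with the same direction where both passed. Another 1026 fell short of it in the same direction, 103 newly passed and 9 changed sign where at least 1 of the fits passed. With PBS, Tgm2 reversed to 0.0114 with median-ratio factors, 0.0099 with limma-voom and 0.0114 with log2 CPM, both on recovered reads. With the length and GC trend removed, Cox5a reversed to -0.0318 and Aprt to -0.0854 with PBS, and Cyba to -0.11, Cox4i1 to -0.0416, Ftl1 to -0.0076 and Aprt to -0.10 with C. albicans, and the cause was not tested. Of the genes that changed sign only Cyba and Aprt passed in the new direction. Requiring a 2-fold change left 284 genes in the wild-type response, 78 in the knockout response, 41 and 121 for the knockout effect with PBS and C. albicans and 91 for the interaction. These 2-fold counts depended on the pseudocount, the values and the filter. In the wild-type response they were 433 and 158 with pseudocounts of 0.1 and 5 and 440 with limma-voom, and in the knockout response 47 with a pseudocount of 5. For the knockout effect with PBS they were 101 and 10 with these pseudocounts, 83 with limma-voom, 76 with log2 CPM, 21 with the CPM filter and 26 without genes under 300 bases, and with C. albicans 217, 42, 228 and 201 with the first 4 of these. For the interaction they were 30 with a pseudocount of 5, 147 with limma-voom, 159 with log2 CPM, 55 with the filter at 5 TPM, 59 at an adjusted p under 0.01 and 149 without wild-type C. albicans replicate 1. An adjusted p under 0.01 left 351 in the knockout response, 2171 for the knockout effect with PBS and 652 for the interaction. The knockout response ranged from 420 to 626 without single libraries (464 without knockout PBS replicate 1, 420 without 3, 468, 532 and 441 without knockout C. albicans 1, 2 and 3) and was 1350 with only its 6 libraries. The interaction ranged from 1036 without knockout PBS replicate 1 to 2531 without wild-type C. albicans replicate 1, and the cause was not tested. The score difference passed an exact permutation test with no fold minimum (-0.23, p = 0.005, the smallest possible), fallen genes only (-0.98, p = 0.005, several of them microRNA genes), median-ratio factors (-0.82, p = 0.01), upper-quartile factors (-0.78, p = 0.025) and without wild-type PBS replicate 1 (-0.84, p = 0.02). In the other alternatives its p was 0.065 to 0.1, and without single libraries the score difference ranged from -0.91 to -0.76. The difference with median-ratio factors was close to the -0.80 of the main fit, so passing or not says little about its size. Lists passing camera numbered 12, 13, 5, 15 and 9 in the wild-type and knockout responses, the knockout effect with PBS and C. albicans and the interaction, and 5, 7, 0, 3 and 5 with an estimated correlation. With fry, which does not compare a list with other genes, they numbered 21, 21 and 17 in the wild-type response, the knockout effect with PBS and the interaction. With the length and GC trend removed 3 passed for the knockout effect with PBS, and without wild-type C. albicans replicate 1, 19 for the interaction. With the replicate number as a replicate block 4919, 716, 3547, 4402 and 1418 genes changed in these comparisons, and the per-number score differences were -0.75, -0.87 and -0.78 (sign-flip exact p = 0.25, the smallest possible). The numbers were not taken to pair the libraries, since same-numbered libraries correlated between -0.0874 and 0.0871 in their deviations over 18 pairs and 0 libraries correlated best with their own number in all other groups. Between the PBS libraries of the genotypes the same-numbered pairs had the highest values, 0.0479, 0.0376 and 0.0871. Scaling by library sizes only equals the main scaling for TPM. The alternatives planned for deposited counts (DESeq2, and edgeR with TMM or other factors) were not run on the recovered reads.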

Other observations

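The trend-removed values and the 3' UTR test were chosen after the results were seen, as were the list counts under each scaling.

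Actin and matrix genes rose more often than they fell with C. albicans in wild type. Of 39 phagocytosis and actin regulators 20 rose and 8 fell with C. albicans (21 higher and 9 lower adjusted over the list alone, camera adjusted p = 2.6e-04, with an adjusted p = 0.123 with an estimated correlation). Actg1, a cytoplasmic actin gene, rose by 0.41, Coro1a, encoding the actin-binding coronin 1A, by 0.39 and the filamin gene Flna by 0.41. In the knockout with C. albicans 4 were higher and 21 lower than in wild type (4 higher and 22 lower adjusted over the list alone, camera adjusted p = 0.00212, with an adjusted p = 0.171 with an estimated correlation), with Flna at -0.63, the vinculin gene Vcl at -0.59 and Iqgap1 at -0.52. Of 19 matrix and matrix protease genes 11 rose and 3 fell in wild type (11 higher and 3 lower adjusted over the list alone), and the list passed camera with both correlations. Plaur, encoding the urokinase receptor, rose by 1.70, the integrin gene Itga5 by 0.73 and Plau, encoding urokinase, by 1.21. The interaction for that list had 3 higher and 6 lower (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00924, with an adjusted p = 0.0526 with an estimated correlation), with Itga5 at -0.53 and Plaur at -0.92.

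Of 30 lysosome and autophagy genes 5 rose and 17 fell in wild type (6 higher and 19 lower adjusted over the list alone, camera adjusted p = 0.0495, with an adjusted p = 0.593 with an estimated correlation). The cathepsin gene Ctsd stood at -0.36, while Sqstm1, encoding the autophagy receptor p62, rose by 1.05. Of 31 cell cycle genes 1 was higher and 11 lower in the knockout with PBS (1 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.551), with the proliferation marker gene Mki67 at -0.78. Of 14 mechanosensitive channel genes 0 were higher and 3 lower in the knockout with PBS (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.761), and these were Piezo1, Pkd1 at -0.58 and Trpm7 at -0.36. Among all 11283 tested genes 2948 were lower in that comparison, so the share in this list was not above the general one. Of 11 YAP-TEAD genes 0 were higher and 5 lower in the knockout with C. albicans (0 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0491, with an adjusted p = 0.271 with an estimated correlation). The members that moved there are kinases and adaptors of the Hippo pathway, Mob1a at -0.75, Sav1 at -0.43, Lats1 at -0.53 and Stk4 at -0.30 among them. Other lists passed camera with the preset correlation and not with the estimated one. In the knockout response, 5 of 27 C-type lectin signalling genes rose and 1 fell (6 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0170, with an adjusted p = 0.132 with an estimated correlation), and 4 and 2 of the matrix list (5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0457, with an adjusted p = 0.119 with an estimated correlation), 4 and 1 of the actin list (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.6e-04, with an adjusted p = 0.125 with an estimated correlation) and 1 and 5 of the lysosome list (2 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0185, with an adjusted p = 0.581 with an estimated correlation). Without wild-type C. albicans replicate 1 in the fit these counts were 7 and 3, 6 and 4, 11 and 2, and 2 and 9. In the knockout with C. albicans 2 of the matrix list were higher and 10 lower (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.0491, with an adjusted p = 0.148 with an estimated correlation). In the interaction 3 of the actin list were higher and 10 lower (5 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0165, with an adjusted p = 0.244 with an estimated correlation) and 5 cell cycle genes higher and 1 lower (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0310, with an adjusted p = 0.281 with an estimated correlation), which were 7 and 16, and 8 and 1, without wild-type C. albicans replicate 1.

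Of the fixed marker lists, 6 of 11 osteoclast genes, 5 of 10 endothelial, 4 of 14 dendritic cell, 3 of 16 neutrophil, 2 of 14 B and plasma cell, 2 of 8 megakaryocyte, 1 of 17 T and NK cell, 1 of 12 erythroid, 1 of 11 mast cell and basophil and 0 of 13 stromal cell genes were tested. Of the 6 osteoclast genes 0 rose and 3 fell with C. albicans in wild type (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0491, with an adjusted p = 0.132 with an estimated correlation) and 0 rose and 1 fell in the knockout (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0170, with an adjusted p = 0.0865 with an estimated correlation), or 0 and 2 without wild-type C. albicans replicate 1 in the fit. Cd4 was at 16.7, 14.4, 8.05 and 11.3 TPM in wild type with PBS and C. albicans and the knockout with PBS and C. albicans. Among the osteoclast genes, in these groups, Atp6v0d2 was at 392, 300.2, 363 and 333 TPM, Acp5 at 81.0, 50.3, 98.0 and 80.5 and Ctsk at 59.5, 58.8, 62.6 and 55.7. Csf3r, a neutrophil marker that macrophages also express, was at 84.9, 65.1, 58.9 and 57.9 TPM, Mmp8 of that list at 6.94, 6.11, 9.0 and 6.34, S100a8 at 2.06, 6.68, 4.51 and 3.54 and the dendritic cell gene Cd24a at 1.33, 6.01, 2.23 and 2.87. With C. albicans in wild type 1 neutrophil gene rose and 1 fell (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.964), 1 dendritic cell gene rose and 2 fell (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.782) and 2 endothelial genes rose and 1 fell (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.771). Some lymphocyte genes, chosen after their values were seen, had low means that were lowest in wild type with C. albicans, at 1.36, 0.206, 0.594 and 0.599 TPM for Cd79a, 1.20, 0.0593, 0.339 and 0.181 for Jchain, 1.02, 0, 0.329 and 0.125 for Thy1, 0.728, 0, 0.403 and 0.244 for Nkg7 and 0.601, 0.0223, 0.0722 and 0.0454 for Gzmb. Of these Cd79a alone was tested, with a fall by 0.97 with C. albicans in wild type (adjusted p = 0.00182). Other lymphocyte genes of the fixed lists, not tested either, were not lowest there. Cd247 was at 0.0439, 0.172, 0.116 and 0.0507 TPM and Vpreb1 at 0.227, 0.420, 0.441 and 0.366 in the same groups. Within 2000000 bases of Piezo1, 16 of 54 tested genes changed in the knockout with PBS, or 29.6% against 32.3% of all genes, and 24 with C. albicans, or 44.4% against 39.9%. Il12b, under the filter, had 6, 97 and 63 reads in wild-type C. albicans replicates 1 to 3 and 3, 8 and 13 in the knockout ones.

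A hypothesis on the long genes, that 3' UTR length rather than gene length as such goes with the lower levels in the knockout, was tested. It is argued against for UTR length alone. With coding length held fixed by rank, fold change with PBS had a partial correlation across 10377 genes of -0.287 with 3' UTR length, and with UTR length held fixed one of -0.468 with coding length. With C. albicans these were -0.314 and -0.327. The hypothesis needs the correlation with coding length to lie near 0, above -0.1, and it was at most -0.327 in both treatments. The bound of -0.1 was written after the values were seen. With C. albicans the correlations with UTR and coding length were close, so neither length stood out there. A part for UTR length beside coding length stays open, and genes are not independent replicates.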
